A study of Mus musculus with 3 samples.

How the data were processed

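Total RNA of 3 mouse samples was measured on 3 single-colour Affymetrix arrays, 1 array per sample. Per the labels' protocols, RNA was extracted with ISOGEN II, fragmented and biotinylated with a whole-transcript terminal labelling kit. The authors deposited 1 intensity per probe set and array, on a linear scale, made with Affymetrix Expression Console per the submitters' processing notes. The version, the summarization method, the background correction and the normalization are not given in the sources used here. The quartiles of the 3 arrays lay close together, with medians of 67.8 for fibroblasts, 71.5 for DiBA and 67.7 for BA, so the intensities were taken as already normalized between arrays. Scanner files were not used here.

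Groups came from the labels. The fibroblast sample is labelled mouse fibroblasts. The second sample carries the name DiBA, and the series title speaks of directly converted brown adipocytes. The third, BA, carries brown adipose tissue as its source and tissue, while its description calls it cultured cells, so whether tissue or cultured cells were used is not settled by the labels. Each group holds 1 array. No spread between replicates could be estimated, no p-value is given, and each difference lacks a replicate check. The number of arrays limits the precision, and every comparison describes these 3 arrays only.

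The table held 28943 probe sets. The platform's probe table listed 23410 of them, of which 21789 had 1 gene symbol and 1621 had several, and 5533 were not listed and stay unnamed here. The first gene identifier was found in the RefSeq gene table of assembly GRCm38.p6 for 23312 of the listed probe sets, and 0 symbols changed through it. That table served for names only. Probe sets with several symbols named no gene. The remaining ones gave 19938 genes, 999 of them with more than 1 probe set, whose log2 values were averaged.

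Values were analysed as log2(intensity + 1), so a fold change is on that scale and understates the change of dim genes. A gene was called higher or lower at a difference of at least 2-fold, where the higher of both arrays reached an intensity of 69.2, the median of all probe sets over the 3 arrays. This filter passed 11621 genes for DiBA against fibroblasts, 11663 for BA against fibroblasts and 11076 for DiBA against BA. Many probe sets carried exactly identical intensities on different arrays: 9677 of them (33.4%) on all 3 arrays, 11421 (39.5%) on DiBA and fibroblasts, 10708 (37.0%) on BA and fibroblasts, and 13686 (47.3%) on DiBA and BA. Such a gene is reported with a difference of 0, which reflects how the deposited values were made and is no measure of how closely the arrays match.

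Before the data were examined, 20 gene lists were fixed. They covered brown, beige, general and white adipocyte genes, adipogenic transcription regulators, fatty acid and triglyceride synthesis, fatty acid oxidation, oxidative phosphorylation with the citric acid cycle, glycolysis, fibroblast and extracellular matrix genes, contractile genes, cell cycle genes, interferon response genes, and inflammatory cytokines with acute phase genes. Markers of macrophages and immune cells, endothelial cells, skeletal muscle, erythrocytes, and Schwann cells, and a housekeeping list, completed the set. A list's median difference was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. That percentile, and the 95% order-statistic interval of a list's median over its genes, describe these arrays, since genes are not replicates. The genes named were also set in advance: 11 genes always, the 8 highest and 8 lowest differences of each pair that pass the filter (leaving out predicted genes, Riken clones, olfactory and vomeronasal receptors, small RNAs and immunoglobulin genes), and 2 to 4 members of each list with the largest differences. Genes named outside this rule are said to be chosen after their values were seen.

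Both comparisons with fibroblasts share 1 array. The correlation, covariance, same-sign share and overlap of their differences were therefore set beside the mean of 100 simulations of unchanged arrays against that shared array, and beside the overlap of independent lists. Intervals of shares are exact binomial 95% intervals over genes. The steps were tested on simulated data for DiBA against fibroblasts with 19938 genes and noise of 0.18 (SD, log2): 2% of 50 genes changed 1.5-fold were called, 40% of 50 changed 2-fold, 98% of 50 changed 3-fold and 98% of 50 changed 4-fold, with 0 unchanged genes called. The noise of 0.18 was the spread of DiBA minus BA over genes, scaled to 1 array. It includes tied values and is no spread between replicates. So small a noise largely sets the count of 0 unchanged genes called, which does not give the error of these arrays. Of 100 random lists, 95% fell between the 2.5 and 97.5 percentiles.

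Alternatives covered centring each array on its median, quantile normalization, no filter and a 75th percentile filter, the highest probe set per gene, keeping probe sets with several symbols, thresholds of 1.5-fold and 4-fold, and log2(intensity + 16). Leaving out probe sets tied between DiBA and BA, and raising intensities under the level filter to it, were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.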

Results

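Gene expression was measured in cultured mouse fibroblasts, in cells named DiBA, and in a brown adipocyte sample named BA whose labelled source is brown adipose tissue. The series title names directly converted brown adipocytes, which sets up 3 comparisons: DiBA with fibroblasts, BA with fibroblasts, and DiBA with BA. Each group was 1 array, so differences are given as log2 differences or folds of intensity without a replicate error. The arrays' median intensities were 67.8 for fibroblasts, 71.5 for DiBA and 67.7 for BA, and 19938 genes were measured.

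The first comparison asks how DiBA differed from fibroblasts. Ucp1, the uncoupling protein of brown fat mitochondria, had an intensity of 23.5 in fibroblasts and 4598 in DiBA, a 188-fold difference. Cidea, a lipid droplet protein of brown fat, was 179-fold higher at 3828, and Adipoq, which encodes the hormone adiponectin, was 369-fold higher at 5849. Pparg, the nuclear receptor that drives adipocyte differentiation, was 25.6-fold higher, and Fabp4, a fatty acid carrier of adipocytes, was 132-fold higher. Col1a1, a chain of type I collagen, was 5.60-fold lower, at 854 against 4780. The fibroblast intensities of Ucp1, Cidea, Adipoq and Fabp4 lay below the median of all probe sets, 69.2, where background sets much of the value, so their folds are imprecise. With intensities under 69.2 raised to it, the folds were 65.6 for Ucp1, 54.6 for Cidea, 83.4 for Adipoq and 100.1 for Fabp4.

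Among the regulators named in advance, Prdm16, a transcriptional regulator of brown adipocyte identity, was 11.4-fold higher in DiBA than in fibroblasts. Cebpb, a transcription factor of early adipocyte differentiation, was 5.19-fold higher. Ppargc1a, a coactivator of mitochondrial genes, was 11.1-fold higher. Dio2, the deiodinase that activates thyroid hormone, differed by 2.41-fold at a low intensity of 108, and by 1.55-fold with that floor. Myc, a growth regulator, was 3.21-fold lower.

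**Figure D1:**
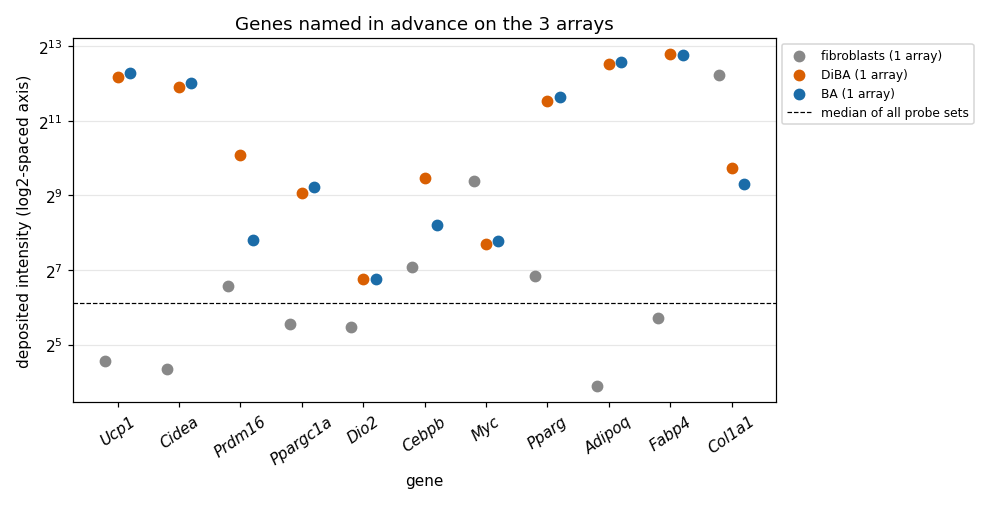
Deposited intensity (log2-spaced axis) of the 11 genes named in advance on the fibroblast, DiBA and BA arrays, 1 point per array, with the median of all probe sets dashed. Ucp1 lies at 23.5 in fibroblasts, 4598 in DiBA and 4995 in BA, while Prdm16 lies at 1084 in DiBA and 223 in BA.

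Over all genes, 1703 were at least 2-fold higher and 1530 at least 2-fold lower in DiBA than in fibroblasts, of which 307 and 82 differed at least 8-fold. The 8 highest were Cyp2e1, a cytochrome P450, at 8.72 (log2), Adipoq at 8.53, Tmem45b at 7.88, Cox8b at 7.76, Ucp1 at 7.55, Cidea at 7.48, Thrsp at 7.40 and Ces1d at 7.32. The lowest were Actg2 at -4.90, Ccn2 at -4.83, Tnmd at -4.73, Cd109 at -4.69, Inhba at -4.63, Tagln at -4.46, Crabp1 at -4.33 and Slc38a4 at -4.33. All 8 highest genes lay under 69.2 in fibroblasts, and 3 of the 8 lowest under it in DiBA, so both orders rest in part on background.

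Adipocyte and mitochondrial lists were higher in DiBA than in fibroblasts. Of 27 general adipocyte genes measured, 26 were at least 2-fold higher and 0 lower, with a median difference of 5.07 (95% interval over genes 4.09 to 6.38). Aqp7, a glycerol channel, differed by 7.27 and Gpd1, an enzyme of glycerol phosphate synthesis, by 7.20. Of 19 brown adipocyte genes, 17 were higher and 0 lower, with a median of 3.47, and Cox7a1 differed by 7.17, with 15 higher when the floor was used. Fatty acid and triglyceride synthesis had 19 of 22 genes higher and 1 lower (Scd2 at -1.38), with a median of 2.43. Fatty acid oxidation had 20 of 22 higher and 0 lower, with a median of 3.21, led by Pdk4 at 5.94 and Ppara at 5.37. Of 41 genes of oxidative phosphorylation and the citric acid cycle, 37 were higher and 0 lower, with a median of 2.06, and Suclg1 differed by 3.43. Of 27 adipogenic regulators, 16 were higher and 2 lower, with a median of 1.40. Each of these 6 medians lay at the 100th percentile of its random lists.

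Of 12 beige adipocyte genes, 4 were at least 2-fold higher in DiBA than in fibroblasts, including Slc36a2 at 5.76 and Car4 at 4.28, and 3 were lower, including Tmem26 at -1.53, with a median of 0. Of 13 white adipose genes, 3 were higher, including Retn at 6.51 and Lep at 4.22, and 4 were lower, including Mest at -2.85, with a median of 0 and a mean of 0.43. Most of these lower calls were near background: with the floor, beige genes had 4 higher and 1 lower, and white adipose genes 2 higher and 1 lower. Of 14 glycolysis genes, 6 were higher, including Pdk1 at 3.40, which encodes a kinase that restrains pyruvate oxidation, and 1 was lower, the glucose transporter gene Slc2a1 at -2.11. Their median was 0.35, at percentile 95.8 of random lists.

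Genes of matrix, contraction and proliferation were lower in DiBA than in fibroblasts. Of 32 fibroblast and extracellular matrix genes, 22 were at least 2-fold lower and 2 higher, with a median of -1.70, and Col12a1 and Tnc lay at -4.09 and -3.97. Of 19 contractile genes, 15 were lower and 0 higher, with a median of -2.97, led by Actg2 and Ccn2. Of 27 cell cycle genes, 26 were lower and 0 higher, with a median of -1.92, and Bub1 and Ccna2 lay at -2.95 and -2.84. All 3 medians lay at percentile 0 of their random lists.

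Markers of other cell types were also higher in DiBA than in fibroblasts, beside the adipocyte genes. Of 19 skeletal muscle genes, 14 were at least 2-fold higher, with a median of 2.45, including the parvalbumin gene Pvalb at 5.40, the fast myosin gene Myh4 at 4.76 and the creatine kinase gene Ckm at 4.70. The 3 lower members were Myod1, Myog and Myh3, the last at -2.18, genes of muscle determination and of embryonic muscle, which were singled out after their values were seen. Of 17 endothelial genes, 13 were higher and 0 lower, with a median of 1.70, including Cdh5, a junction protein of endothelial cells, at 4.94 and Esam at 3.11. Of 21 macrophage and immune genes, 19 were higher and 0 lower, with a median of 1.65, including the antigen presentation genes H2-Aa at 4.70 and Cd74 at 4.61. These 3 medians lay at the 100th percentile. With the floor, 14 muscle genes were higher and 1 lower, 11 endothelial and 17 macrophage genes higher.

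Of 20 interferon response genes, 3 were at least 2-fold higher in DiBA than in fibroblasts, including Ifi27l2a at 5.58, and 0 lower, with a median of 0.03 that became -0.05 when each array was centred and 0 with the floor, where 2 genes were higher. Of 21 inflammatory and acute phase genes, 4 were higher, including Lcn2 at 6.72, Orm1 at 6.10 and Hp at 5.97, and 4 lower, including the chemokine gene Ccl7 at -3.34, with a median of 0.24, at percentile 99.9 of random lists, which was 0 with low intensities raised to 69.2. For the inflammatory list, the central range of random medians was -0.09 to 0, so any median above 0 lay beyond it. Its interval over genes was -0.23 to 0.83. Of 4 erythrocyte genes measured, 1 was higher, the haem synthesis gene Alas2 at 3.28, with a median of 0.09. Of 7 Schwann cell and neural genes, 0 reached 2-fold, with a median of -0.05. Of 11 housekeeping genes, 0 reached 2-fold, with a median of -0.28, at percentile 28.0. Ywhaz, at -0.98, passed 2-fold under 2 alternatives, at -1.05 with centred arrays and -1.07 with the highest probe set per gene.

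The second comparison asks how BA differed from the same fibroblasts. Ucp1 was 204-fold higher in BA at an intensity of 4995, Cidea 194-fold, Adipoq 381-fold and Fabp4 131-fold. Pparg was 27.6-fold and Ppargc1a 12.4-fold higher. Prdm16 and Cebpb were 2.35-fold and 2.16-fold higher, and Dio2 had the intensity it had in DiBA. The limit that low fibroblast intensities set on these folds applies here too, with 71.2 for Ucp1 and 86.2 for Adipoq when the floor is used. Col1a1 was 7.49-fold and Myc 3.04-fold lower.

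In BA, 1897 genes were at least 2-fold higher and 1913 at least 2-fold lower than in fibroblasts, of which 370 and 249 differed at least 8-fold. The 8 highest genes were those of DiBA, from Cyp2e1 at 8.78 to Ces1d at 7.46. The lowest were Thbs1, a matrix glycoprotein gene, at -7.37, Xist, the RNA that silences an X chromosome in female cells, at -6.25, Crabp1 at -6.01, Slit2 at -5.95, the growth factor gene Igf2 at -5.81, Col12a1 at -5.47, Ccn2 at -5.33 and P4ha3 at -5.33. Of these 8, 4 lay under 69.2 in BA, and with the floor Thbs1 was at -7.06, Slit2 at -5.16, Xist at -4.64 and P4ha3 at -4.50, which changes their order.

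By list, BA had medians of 5.36 for general adipocyte genes (26 of 27 higher), 3.63 for brown adipocyte genes (17 of 19), 2.57 for fatty acid and triglyceride synthesis (20 of 22, 1 lower), 3.40 for fatty acid oxidation (20 of 22, 1 lower), 2.22 for oxidative phosphorylation and the citric acid cycle (37 of 41) and 1.28 for adipogenic regulators (17 of 27, 3 lower). Glycolysis had a median of 0.44, with 6 of 14 genes higher and 1 lower. Beige and white adipose lists had medians of 0, with 4 higher and 3 lower, and 3 higher and 4 lower. With the floor, each had 1 lower gene, beside 4 and 3 higher. The white list had a mean of 0.36.

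The matrix list had a median of -2.33 in BA against fibroblasts, with 25 of 32 genes lower and 2 higher, the contractile list -3.50 with 15 of 19 lower, and the cell cycle list -3.04 with 26 of 27 lower. With the floor, the contractile median was -3.17 and the cell cycle median -2.42, with the same counts. Skeletal muscle genes had a median of 2.62 with 14 of 19 higher and 3 lower, endothelial genes 2.02 with 14 of 17 higher, and macrophage and immune genes 1.65 with 16 of 21 higher. Interferon genes had a median of 0.06 with 3 of 20 higher. Inflammatory genes had a median of 0 and a mean of -0.17, with 2 of 21 higher and 6 lower. Erythrocyte genes had a median of 0.10 with 1 of 4 higher, Schwann cell genes -0.05 with 0 of 7 at 2-fold, and housekeeping genes -0.39 with 1 of 11 lower, Ywhaz at -1.19.

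Most genes that set BA apart from fibroblasts differed in the same direction in DiBA. Of the 1897 genes higher in BA, 1656 (87.3%, interval 85.7 to 88.8) were also at least 2-fold higher in DiBA, against 276 for independent lists. Of the 1913 lower genes, 1498 (78.3%, interval 76.4 to 80.1) were also lower in DiBA, against 250 for independent lists, and 0 genes were called in opposite directions. At a 4-fold threshold for both, the share of lower genes was 53.7%. The differences correlated at r = 0.977 across genes, with a covariance of 0.98, where unchanged arrays sharing 1 fibroblast array gave 0.501 and 0.03. The simulated noise was taken from the DiBA minus BA differences over all genes, ties included. How close those 2 arrays lay therefore set the 0.03, which is no estimate from replicates. The single fibroblast array could not be split, so part of the excess may come from that shared array.

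**Figure D2:**
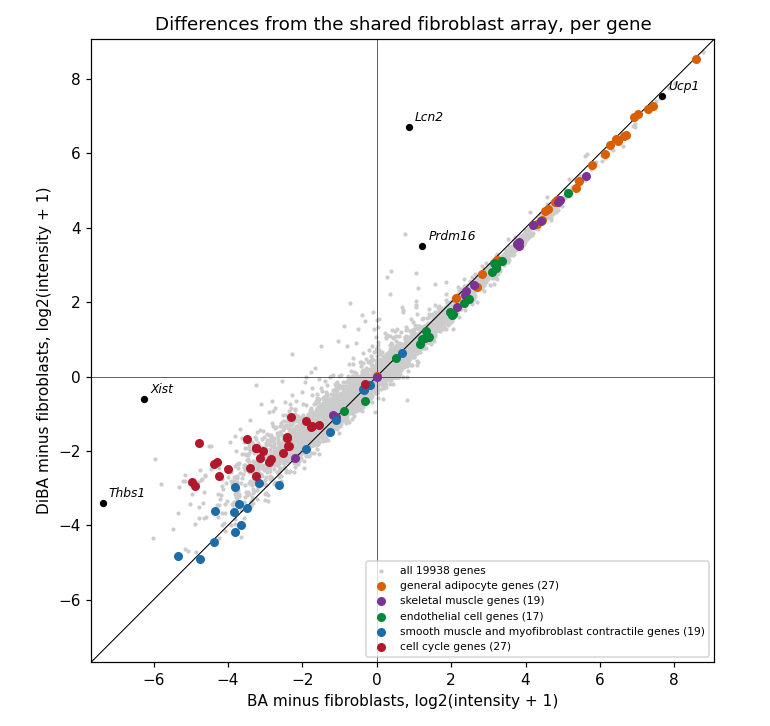
Each point is 1 of 19938 genes, with its log2 difference of BA minus fibroblasts on the x axis and of DiBA minus fibroblasts on the y axis, the line marks equal differences, and 5 gene lists are coloured. Adipocyte, endothelial and skeletal muscle genes lie near the line, and most cell cycle genes, with Lcn2, Prdm16, Thbs1 and Xist, lie above it.

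The third comparison sets DiBA directly against BA. Lcn2, which encodes the secreted protein lipocalin 2, was 58.2-fold higher in DiBA, with an intensity of 3472 against 58.7 in BA and 31.9 in fibroblasts. Prdm16 was 4.85-fold and Cebpb 2.40-fold higher in DiBA than in BA. Ucp1, Cidea, Adipoq, Pparg, Fabp4, Ppargc1a, Dio2 and Myc differed by at most 1.12-fold, and Col1a1 was 1.34-fold higher in DiBA.

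In all, 194 genes were at least 2-fold higher and 0 at least 2-fold lower in DiBA than in BA, and with a 75th percentile filter 76 were higher. After Lcn2 at 5.86, the highest were Xist at 5.65, Thbs1 at 3.96, Slit2 at 3.74, the matrix protease gene Mmp9 at 3.07, Agtr2 at 3.04, the proliferation marker Mki67 at 3.01 and Igf2 at 2.92. Of these 8, 6 lay under 69.2 in BA, so their values and order rest in part on background. With the floor, 137 genes were higher and 0 lower, with Lcn2 at 5.63, Xist at 4.04, Thbs1 at 3.65, Slit2 at 2.94, Mki67 at 2.01 and Agtr2 at 1.37. Of the 194, 170 were also at least 2-fold higher in fibroblasts than in BA. The lowest differences were Acot4 at -0.76, Cib4 at -0.70, Paqr6 at -0.67, H2-DMa at -0.62, Cox6b2 at -0.61, and Gstm6, Npr1 and Rnf182 at -0.60. The arrays of DiBA and BA correlated at r = 0.993 across genes, against 0.895 for DiBA with fibroblasts and 0.865 for BA with fibroblasts, and genes are not independent replicates.

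Of 27 cell cycle genes, 11 were at least 2-fold higher in DiBA than in BA and 0 lower, with a median of 0.93 and Mki67 and Ccna2 at 3.01 and 2.13. Of the 27, 17 lay under 69.2 in BA, and with the floor 6 were higher, the median was 0.60, and Mki67 and Ccna2 were at 2.01 and 1.33. Of 32 matrix genes, 5 were higher and 0 lower, with a median of 0.43, including Thbs1, the collagen crosslinking enzyme gene Lox at 2.52 and the fibronectin gene Fn1 at 1.72. Of 21 inflammatory and acute phase genes, 4 reached the threshold and the level filter, with a median of 0.31, including Lcn2 and the prostaglandin synthase gene Ptgs2 at 2.36. With the floor 3 reached it, Ptgs2 was at 1.62 and the median was 0. As deposited, these 3 medians lay at the 100th percentile. With many values tied between DiBA and BA, the central range of random medians was 0 to 0 for cell cycle and inflammatory genes. For matrix genes it was -0.06 to 0. Any median above 0, however small, would lie beyond these ranges, so the percentile does not show the size of a difference. Intervals over genes were 0.59 to 1.53 for cell cycle, 0.14 to 0.63 for matrix and -0.0013 to 0.78 for inflammatory genes. The last interval includes 0. Of 19 contractile genes, 0 reached 2-fold, with a median of -0.05, at percentile 2.23, and a mean of 0.06.

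The adipocyte lists had medians at or slightly below 0 between DiBA and BA. Of the 370 genes at least 8-fold higher in BA than in fibroblasts, 357 were lower in DiBA than in BA. Choosing genes for a high BA value favours a lower value in DiBA, so this count alone shows no shortfall. General adipocyte genes had a median of -0.11, fatty acid synthesis -0.13, fatty acid oxidation -0.13, oxidative phosphorylation -0.13 and glycolysis -0.09, with 0 genes at 2-fold in any. Against random lists, general adipocyte genes lay at percentile 7.78 and glycolysis at 17.6, inside the central 95%, while fatty acid synthesis lay at 1.84, fatty acid oxidation at 1.61 and oxidative phosphorylation at 0.32. Brown adipocyte genes had a median of -0.16, at percentile 0.15, with Prdm16 as the 1 higher gene. Adipogenic regulators had -0.08, at percentile 1.435, with a mean of 0.06 and 2 higher genes, Prdm16 and Cebpb. Beige genes had a median of 0, and white adipose genes -0.06, at percentile 2.445, with a mean of 0.07 and 1 higher gene, Mest at 1.97. When each array was centred, the medians of fatty acid synthesis, fatty acid oxidation and oxidative phosphorylation became -0.21. A comparison chosen after seeing the results used 284 other genes at least 8-fold higher in BA than in fibroblasts. Their median was -0.22. At matched BA level, list members at least 2-fold higher in BA deviated from them by small positive medians. These were 0.02 for brown adipocyte (interval -0.06 to 0.06), 0.04 for general adipocyte, 0.03 for fatty acid oxidation and 0.01 for oxidative phosphorylation genes. The reference genes were chosen at 8-fold and the list members at 2-fold. The stronger choice for a high BA value favours a lower reference, so these small deviations do not show whether the lists fell short.

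The markers of other cell types had 0 genes at 2-fold between DiBA and BA. The median was -0.18 for skeletal muscle and -0.27 for endothelial genes, both at percentile 0 of their random lists, with 14 of 19 and 16 of 17 genes lower in DiBA. Macrophage and immune genes had a median of -0.09, at percentile 1.03. Ckm had an intensity of 2489 in DiBA and 2805 in BA, Cdh5 of 1027 and 1188, and Lyz2, a macrophage lysozyme gene chosen as the brightest of its list, of 1635 and 1463. Medians were -0.02 for erythrocyte genes, 0 for Schwann cell genes, -0.01 for interferon genes and 0.04 for housekeeping genes, the last -0.04 with centred arrays.

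**Figure D3:**
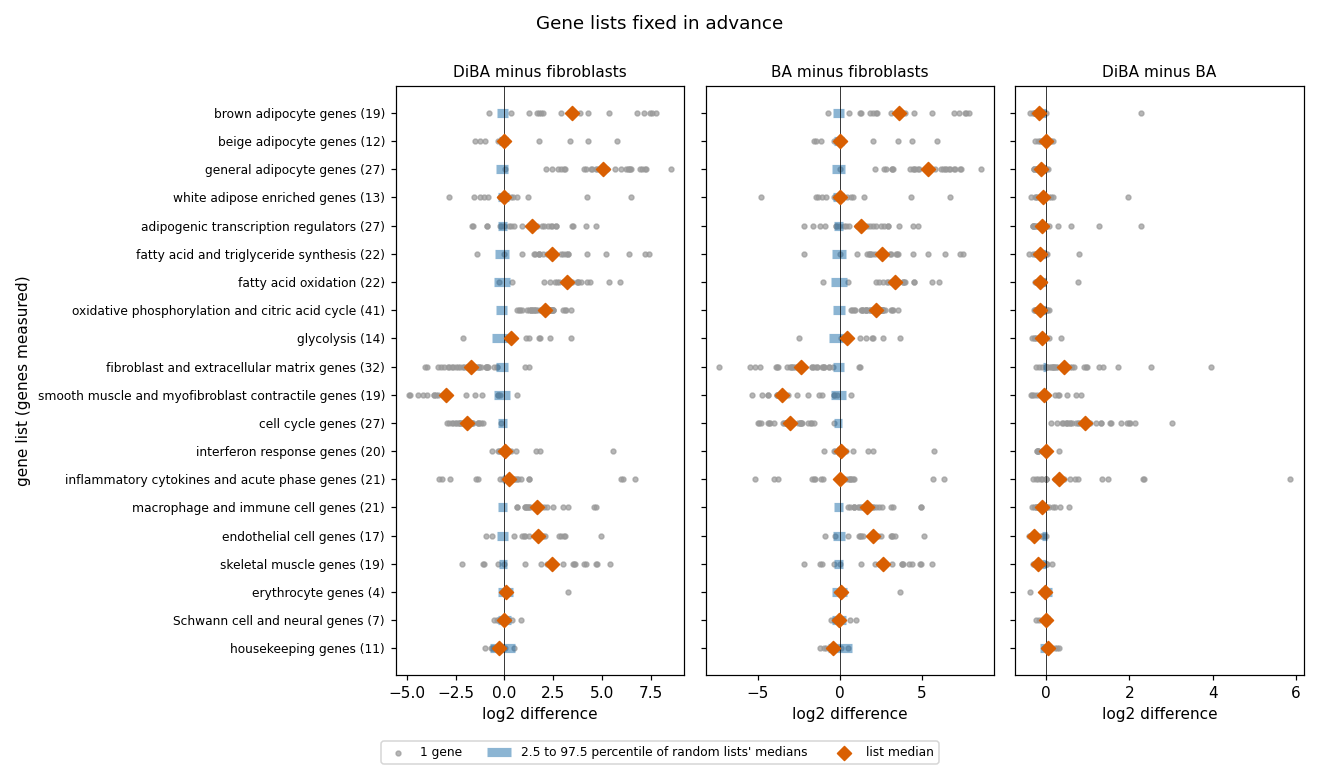
Log2 differences of the genes of 20 lists (grey points), their medians (diamonds) and the central 95% of random lists' medians (blue bars), in 1 panel per pair of arrays whose x axes differ. Between DiBA and BA the cell cycle median is 0.93, and the general adipocyte median is -0.11.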

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

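Probe sets without a listed gene were not part of the comparisons above. Of 5533 such probe sets, 1800 passed the level filter on the DiBA or fibroblast array, and 271 of these were at least 2-fold higher and 130 at least 2-fold lower in DiBA than in fibroblasts. Against BA, 38 were at least 2-fold higher in DiBA and 0 lower, and 30 of the 38 were also at least 2-fold higher in fibroblasts than in BA. What these probe sets measure was not analysed here.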

How the results depend on the processing

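Under the alternatives that were run, 0 named genes and 0 list medians with differences of at least 1 (log2) reversed. The level filter and the threshold do not enter list medians, correlations or single genes, so those alternatives gave no other value there. Leaving out probe sets tied between DiBA and BA, and raising intensities under the level filter to it, were chosen after seeing the data. Leaving out a replicate was not possible because each group holds 1 array. No paired analysis was possible because each group holds 1 array. At a 4-fold threshold, the counts of higher and lower genes were 731 and 372 for DiBA against fibroblasts, 862 and 674 for BA against fibroblasts, and 33 higher for DiBA against BA. At 1.5-fold, 2747 genes were lower in DiBA and 3049 in BA than in fibroblasts, and 456 were higher and 11 lower in DiBA than in BA. A threshold of another size changes such counts by construction. Against BA, a 75th percentile filter left 76 higher genes in DiBA, and no filter gave 1 lower gene. The share of genes higher in BA that were also higher in DiBA was 81.8% with centred arrays, 85.0% with quantile normalization, 85.0% with a 75th percentile filter, 90.5% at 1.5-fold and 83.3% at 4-fold. For lower genes it was 83.7%, 80.7%, 81.1%, 87.7% and 53.7%. With low intensities raised, 137 genes in place of 194 were higher in DiBA than in BA, 6 in place of 11 of them cell cycle genes, and the share was 85.6% for higher genes, and the correlation with fibroblasts was 0.818 for DiBA and 0.772 for BA. Without tied probe sets, the correlation with fibroblasts was 0.802 for DiBA and 0.746 for BA. Centring moved the DiBA minus BA medians of fatty acid synthesis to -0.21, fatty acid oxidation to -0.21, oxidative phosphorylation to -0.21, endothelial genes to -0.35, skeletal muscle genes to -0.26 and housekeeping genes to -0.035, and the DiBA minus fibroblasts median of interferon genes to -0.050, the last 2 with a change of sign. Centring shifts the median of all genes by -0.08 for both pairs with DiBA. Where no construction is named, the cause was not tested. Signal near background limits the folds of genes that are dim on 1 array.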

Other observations

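Imprinted genes of growth regulation, a set chosen after their values were seen, were mostly highest in fibroblasts and lowest in BA, an order held by 11 of 13 measured. Of the 13, 11 were at least 2-fold lower in DiBA than in fibroblasts and 11 in BA, with medians of -2.35 and -3.81, and 5 were at least 2-fold higher in DiBA than in BA. Igf2 had intensities of 5998 in fibroblasts, 809 in DiBA and 106 in BA, Mest of 2668, 370 and 93.8, Peg10 of 1663, 552 and 117, and Dlk1, an inhibitor of adipocyte differentiation, of 2878, 440 and 179. Slc38a4, at 1196, 58.7 and 62.2, and Ndn, at 1036, 775 and 775, did not follow this order, and Sgce followed it only within 737, 632 and 624. MHC class II genes, chosen likewise, had 5 of 7 at least 2-fold higher in both DiBA and BA than in fibroblasts, with H2-Ea at 22.1 in fibroblasts, 1278 in DiBA and 1537 in BA.

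In DiBA, 20 genes stood at least 2-fold above both other arrays, 16 of them also with low intensities raised to 69.2. Beside Lcn2, Mmp9, Prdm16 and Cebpb, they included Atp6v0d2, a proton pump subunit of osteoclasts, at 5.53-fold over the higher of the others (2.97-fold with that floor), Fgl1 at 5.32-fold (2.29-fold), Slfn4 at 3.62-fold (2.31-fold), Mmp12, a macrophage elastase gene, at 3.35-fold (2.40-fold), and Lbp, which binds bacterial lipopolysaccharide, at 3.32-fold. Pi15 at 3.97-fold (2.81-fold with the floor), Nptx1 at 3.13-fold (2.90-fold) and Sned1 at 2.44-fold were also among the 20. Those from Atp6v0d2 on were chosen after their values were seen.

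All tests of explanations below were chosen after the results were seen. The first pattern is how close DiBA lay to BA, skeletal muscle and endothelial genes included. Among the 28 genes of those 2 lists that were at least 2-fold higher in BA than in fibroblasts, the median of DiBA minus fibroblasts was 2.62 (interval 1.87 to 3.52), and 27 reached 2-fold (with the floor, 2.14, interval 1.70 to 2.98, and 25), which argues against a conversion of fibroblasts to brown adipocytes alone as the source of these genes. The 28 genes were chosen on the same fibroblast array, and low values there favour both the choice and this median. Without that choice, the 17 endothelial genes had a median of 1.70 (interval 1.01 to 2.80). The 19 muscle genes had 2.45 (0 to 4.08). Brown adipose tissue RNA in the DiBA sample is a candidate explanation: the DiBA minus BA difference of the 28 genes deviated by a median of -0.0014 from the trend of 284 other genes at least 8-fold higher in BA at matched level. Medians of 10000 random sets of 28 trend genes ran from -0.043 to 0.036 (central 95%). The 284 trend genes are on none of the fixed lists and were not sorted by cell type. Lying on their trend therefore does not show that the 28 genes follow adipocyte genes. The trend genes were also chosen at 8-fold and the 28 genes at 2-fold, and a stronger choice for high BA values favours a lower trend. The 16 macrophage and immune genes at least 2-fold higher in BA lay 0.17 above the same trend (interval 0.05 to 0.29). Their random sets ran from -0.068 to 0.058, so not all markers of other cell types lay on the trend. Of the markers, 1 endothelial gene is also on another list, and the BA array itself has all 17 endothelial and 14 of 19 muscle genes above the level filter. The fibroblast array has 8 endothelial and 13 muscle genes above it, so passing the filter does not set muscle genes apart. For adipocyte genes alone, whose median was -0.11, conversion and added tissue RNA cannot be told apart, since both predict levels near BA. Exactly identical values from summarization do not account for the overlap, as 29 of the 1897 genes higher in BA had only tied probe sets, and the share was 87.0% without them. Values made close but not identical by summarization were not tested.

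The second pattern is the 194 genes higher and 0 lower in DiBA than in BA. Fibroblast RNA at 1 common share in the DiBA sample was tested on genes at least 8-fold higher in fibroblasts than in BA. The implied share was 1.06% for 11 contractile genes (interval -1.68 to 3.41) and 13.7% for 14 cell cycle genes (interval 9.87 to 17.8), with 7.23% for 9 matrix genes (3.15 to 13.6), which overlaps both, and 8.18% for all 249 genes (quartiles 3.61 and 13.0). Xist alone implied 65.6% (64.7% with the floor), and Agtr2 84.1% (78.7%). The contractile and cell cycle intervals do not overlap as deposited, but do with low intensities raised to 69.2, where contractile genes gave 1.06% (-0.31 to 3.41) and cell cycle genes 9.39% (3.08 to 14.9), so that comparison leaves 1 common share open. Raising low BA values pulls a positive share down by construction. The overlap runs only from 3.08 to 3.41, and such an overlap does not show that the shares are equal. Xist and Agtr2 go against 1 common share, but as the 2 highest of 249 genes on single arrays they do not decide it. The floor was added to this test after the intervals as deposited, which alone argued against 1 share, had been seen. For the 20 genes above both arrays, the question stays open, since 1 array per group gives no spread between separate samples. A mixture of exactly the fibroblast and BA RNA measured here would hold no gene above both. Still, no count above 0 could have decided this test, as it was set to need replicates. A second brown adipose tissue sample of 1 animal is argued against by Xist, 5.65 above its lowest array in DiBA (4.04 with the floor), together with Eif2s3y, Kdm5d and Uty, Y-linked genes at a median of 1.5 above theirs. The bound was first set on each of the 3 genes and then on their median, as Kdm5d lay 0.92 (log2) above fibroblasts in DiBA. Under the first bound, the test would not have argued against such a sample. BA itself was 2.01-fold above fibroblasts for Kdm5d. Intensities in fibroblasts, DiBA and BA were 187, 603 and 678 for Eif2s3y, 94.35, 179 and 190 for Kdm5d, and 112, 319 and 373 for Uty. For Xist they were 1748, 1155 and 22.0. Fibroblasts were thus highest for Xist and lowest for the Y-linked genes, and BA the reverse. Differences between those 2 arrays therefore also hold sex-linked ones. Conversion of fibroblasts, the difference named by the series title, stays open as a biological explanation, as do pooled animals, which were not tested. The Y-linked levels of DiBA, near those of BA, limit conversion if the arrayed fibroblasts were its source.

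The third pattern concerns genes of osteoclasts and lysosome-rich macrophages, listed after Atp6v0d2 was seen, of which 3 of 11 were at least 2-fold higher in DiBA than in BA and 0 lower. One of them, Gpnmb, was as bright in fibroblasts, at 540 against 493 in DiBA and 90.9 in BA, which leaves Atp6v0d2 and Mmp12. More macrophage-type cells in the DiBA sample may be a source. The fixed macrophage and immune list, which shares 0 genes with other fixed lists, had a median of -0.091 in DiBA minus BA, below its random lists, whereas its 16 members higher in BA than in fibroblasts lay a median of 0.17 (interval 0.05 to 0.29) above the level-matched trend. The second measure was added after the first had been seen and read as arguing against such cells. Random lists were drawn from all genes, whereas 284 other genes at least 8-fold higher in BA had a median of -0.22. A median below random lists therefore does not argue against such cells. The second measure lies in their direction, but it was added late. It also sets members chosen at 2-fold against genes chosen at 8-fold. So the question stays open. Acp5 had intensities of 1400 in DiBA and 1572 in BA, and Lyz2 of 1635 and 1463.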
